A study of Homo sapiens with 6 samples.

How the data were processed

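Poly(A) RNA of HEK293 cells was read from libraries made with a TruSeq RNA kit, after siRNA transfection with Lipofectamine RNAiMAX and lysis in TRIzol 48 hours later. There were 6 libraries in 3 groups of 2. The title and the genotype field of the knockdown records name the circular RNAs the other way round from each other, so the records were read by title and library identifier.

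The deposited counts are fragments per gene made with featureCounts 1.6.0 per the file headers, on primary alignments with both ends mapped and without a strand setting. The authors' processing notes name STAR, featureCounts, DESeq2 and hg19, and their versions were not given in the sources used here, apart from that of featureCounts. The deposited signal columns are counts that the authors divided by 1 size factor per library, separately in each table. The log2 fold changes with their standard errors, the Wald score and the p-value columns were computed by the authors with DESeq2, and the deposited tables hold genes past their adjusted threshold only, so genes outside it are not known from them. The tests here ran on the counts alone, although the deposited values, matched to count columns, gave the grouping by table names.

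The count table held 63677 genes, of which 52181 were matched to a symbol with GENCODE release 29 and 21724 had no fragment in any library. Coordinates are those of the count file (hg19). The 37 genes of the mitochondrial sequence and 5941 genes on other sequences outside the chromosomes had 0 fragments, so mitochondrially encoded mRNAs were not analysed here. Fragments assigned to genes numbered 37379217, 39637733, 38995742, 38108240, 39073508 and 39188378 in control, siRAB3IP and siCAMSAP1 replicates 1 and 2 of the deposited tables. A floor of 3 counts stood for 0.0757 to 0.0803 CPM.

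Each normalized column of the deposited tables was matched to the count column of which it is a multiple, with a tolerance of 1e-09 in log2 ratio, and all 6 matched. In 4 libraries the table name and the sample record disagreed. The grouping by sample records was planned before the data were examined, and the grouping by table names was added after seeing the data.

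Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, its default filter on low counts, quasi-likelihood test, 1 model over 3 groups with 3 residual degrees of freedom) on 22331 genes. P-values were adjusted by the Benjamini-Hochberg method at 0.05. SE stands for the standard error of the log2 fold change. Of 35 gene lists written before the data were examined, 33 had at least 5 members tested. Of 899 list entries, 891 were matched to a gene. Lists were tested with camera in limma 3.58.1 with the preset correlation of 0.01, with an estimated correlation, and with fry. Camera sets the members of a list against all other genes. With an estimated correlation it relies on the 3 residual degrees of freedom, and the simulations below tested the preset correlation only. Named genes were, by a rule fixed in advance, the host genes, the 10 largest called rises and falls per knockdown and 5 between knockdowns among genes with a mean of at least 5 CPM and both libraries of one group on the same side of both of the other, and up to 4 called members per list. Some genes that the rule names are not reported here. Chosen after their values were seen were MAP2, the genes listed as called in both knockdowns, the genes with a matching 3' UTR word that are named, and the 15 genes of the figure by library.

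Alternatives were RLE and upper-quartile scaling, no filter (at least 1 fragment), a stricter filter (mean of at least 5 CPM), a fit of the compared groups alone, a replicate block, DESeq2 1.42.0, limma-voom, glmTreat against a fold of 1.2, removal of the trend with gene length and GC content (fitted on log2 CPM with a prior count of 2), and leaving out each library. The correlation and covariance between knockdowns were set against 20 simulations of unchanged groups sharing their controls. Words of 7 bases in annotated 3' UTRs were scored in 12743 genes with a mean of at least 1 CPM against 100 shuffles. The siRNA sequences were not used here. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures.

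The tests were checked on simulated data with the spread of these libraries, with 5 draws. For siRAB3IP against control, 14.8% of genes changed 1.25-fold, 65.2% changed 1.5-fold and 88.0% changed 2-fold were recovered. For siCAMSAP1 the shares were 13.2%, 64.8% and 87.6%, and with the spread of the grouping by sample records 2.0%, 20.8% and 66.4%. Of the genes called, 7.4%, 8.3% and, with the spread of the sample records, 14.6% had not been changed, above the nominal level. A list of 30 genes moved 1.3-fold was called in 5 of 5 draws, and 0 of 170 unchanged lists were called by camera. The simulated genes were drawn independently, so these draws do not check camera on lists whose genes move together.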

Results

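Poly(A) RNA of HEK293 cells, a human embryonic kidney line, was sequenced 48 hours after transfection with siRNA. One siRNA was aimed at circRAB3IP and another at circCAMSAP1, which are circular RNAs of the RAB3IP and CAMSAP1 genes, and the remaining group received a control siRNA. The series title places circRAB3IP in the context of proliferation, gene expression and mRNA processing, and the design sets each knockdown against the control and allows the knockdowns to be set against each other. There were 6 libraries, 2 per group, with 37379217 to 39637733 fragments assigned to genes in each. The 10 most abundant genes took 13.0% to 14.9% of the fragments. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

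Read by title, the sample records place 4 of the 6 libraries differently from the authors' deposited tables. The genotype field swaps the names of the knockdowns, which changes which libraries disagree but not which are grouped together. Each normalized column of the deposited tables equals 1 column of the count table up to a single factor, and for 4 libraries the name of that column is not the title of the sample record that lists the library. Grouped by the sample records, as planned before the data were examined, edgeR's quasi-likelihood test called 0 of 22331 genes in each of the 3 comparisons. Unadjusted p was under 0.05 for 330, 437 and 456 genes in circRAB3IP against control, circCAMSAP1 against control and circRAB3IP against circCAMSAP1, and DESeq2 called 0, 1 and 0 genes. Those counts are 1.48%, 1.96% and 2.04% of the genes, below the share of 0.05 that unchanged genes give on average. With no filter on low counts edgeR called 5, 21 and 14. Camera with its preset correlation still called 10, 11 and 8 gene lists in this grouping, and 0 with an estimated correlation, as did fry. Everything from here on uses the names of the authors' deposited tables (control, siRAB3IP and siCAMSAP1), a grouping chosen after seeing the data and a departure from the plan, and which of the 2 sets of names is right was not given in the sources used here.

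The linear transcripts of the host genes stayed close to control. RAB3IP, which encodes an activator of the small GTPase RAB8 (hg19 chromosome 12, 70132461 to 70216984), had 59.98 ± 3.56 CPM (counts scaled to library size; SD, n = 2) in control, 67.4 ± 0.987 in siRAB3IP and 58.9 ± 3.71 in siCAMSAP1. CAMSAP1, which encodes a protein that binds microtubule minus ends (chromosome 9, 138700333 to 138799074), had 137 ± 1.53, 153 ± 4.10 and 139 ± 0.817 CPM. The log2 fold changes of RAB3IP were 0.17 ± 0.08 (SE) in siRAB3IP and -0.03 ± 0.08 in siCAMSAP1, with Benjamini-Hochberg adjusted p of 0.225 and 0.944 by edgeR's quasi-likelihood test. For CAMSAP1 they were 0.16 ± 0.07 and 0.02 ± 0.07, with adjusted p of 0.187 and 0.951 by the same edgeR test. With a replicate block in the model, 1 of these host genes passed the threshold in siRAB3IP. Poly(A) libraries read linear mRNA, so these values check neither the knockdown of the circular RNAs nor the labels.

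In the siRAB3IP libraries, targets of NF-kB and ATF4 were among the rises, and CCND1, MARCKS and SGPL1 among the falls. TNFRSF9, a co-stimulatory receptor of the TNF receptor family, rose 6.88-fold, from 1.83 ± 0.255 to 12.5 ± 0.408 CPM (SD, n = 2 each). The NF-kB subunit RELB rose 3.01-fold and the cytokine IL32 rose 2.96-fold, while the growth factor BMP2 went from 25.3 ± 2.17 to 77.5 ± 9.31 CPM. CCND1, which encodes cyclin D1 of the G1 phase, fell from 116 ± 7.62 to 51.3 ± 0.887 CPM. MARCKS, a membrane-bound substrate of protein kinase C, fell from 237 ± 12.2 to 93.8 ± 7.61 CPM, and SGPL1, the sphingosine-1-phosphate lyase, fell from 90.0 ± 6.52 to 33.5 ± 0.907 CPM. CCND1 and SGPL1, and RASSF2, HNRNPF, SESN1, RAB8B and WTIP named below, hold the word TGACTTAA in the 3' UTR. Its carriers were called lower in 21.5% of cases, against 7.1% of genes with neither of its 7-base words. Off-target falls of these genes were therefore not told apart from other causes.

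Over all genes, 2671 of 22331 differed between siRAB3IP and control by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 1469 rose, 1202 fell and 389 changed over 2-fold. With upper-quartile scaling falls were the larger part, with 1296 genes higher and 1412 lower. Protein-coding genes made up 2389 of the 2671. Over 17 alternatives the count ran from 702, against a minimum fold of 1.2, to 5590, with a replicate block. Among genes with a mean of at least 5 CPM, the limit set for naming genes, the largest log2 rises were those of the chemokine CXCL8 (3.03 ± 0.56), TNFRSF9 (2.78 ± 0.16), the axonemal dynein heavy chain DNAH17 (2.34 ± 0.12), BMP2 (1.61 ± 0.10), RELB (1.59 ± 0.16), IL32 (1.56 ± 0.09), the carboxypeptidase CPA4 (1.49 ± 0.20), the sodium-proton exchanger SLC9A2 (1.48 ± 0.17), the matricellular protein THBS2 (1.42 ± 0.13) and the presynaptic scaffold PCLO (1.40 ± 0.13). The largest falls were those of the Wnt inhibitor CXXC4 (-1.86 ± 0.28), the endocytic adaptor STON1 (-1.56 ± 0.21), RASSF2 (-1.44 ± 0.16), SGPL1 (-1.42 ± 0.09), NYNRIN (-1.40 ± 0.13), MARCKS (-1.34 ± 0.09), LRATD2 (-1.27 ± 0.12), the pro-apoptotic BMF (-1.27 ± 0.16), CCND1 (-1.18 ± 0.08) and the non-coding HOTAIRM1 (-1.16 ± 0.12). Reads were counted without strand, so DNAH17, which overlaps PGS1, THBS2, which overlaps THBS2-AS1, and HOTAIRM1, which overlaps HOXA2, are uncertain. CXCL8 rested on unequal siRAB3IP libraries (22.7 ± 13.96 CPM against 2.79 ± 0.899 in control), with an adjusted p of 0.0385 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its call ended without either control library or either siCAMSAP1 library, with no filter on low counts, by limma-voom, and with the length and GC trend removed. The count of called genes was 1307 without siRAB3IP replicate 1, 1160 without siRAB3IP replicate 2, 1680 without control replicate 2, and 702 against a minimum fold of 1.2.

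**Figure D1:**
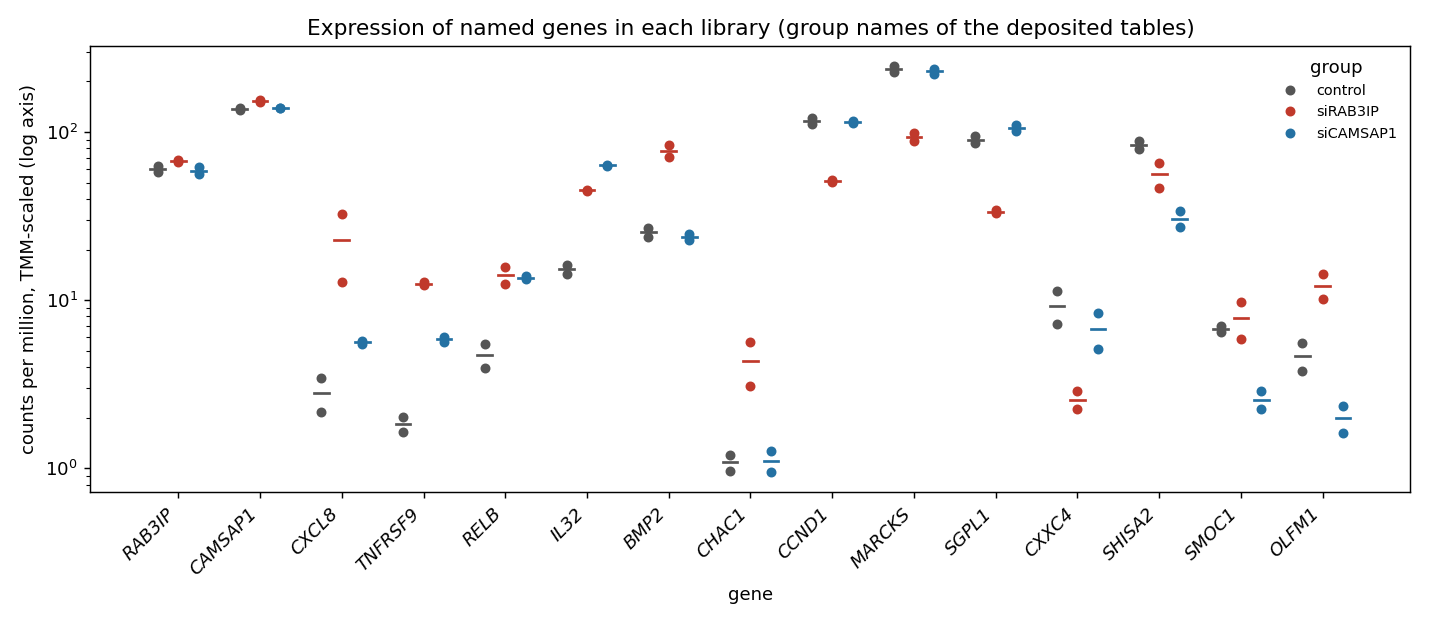
TMM-scaled CPM (log axis) of 15 genes, chosen after their values were seen, in each of the 6 libraries, with 1 point per library, a horizontal line at the mean of each group, and the group names of the deposited tables. TNFRSF9 lay at 12.5 CPM on average in siRAB3IP, 5.84 in siCAMSAP1 and 1.83 in control, and CCND1 at 51.3, 115 and 116.

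Targets of NF-kB rose together in siRAB3IP. Of 21 members, 14 rose (16 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 6.05e-19, adjusted p = 0.206 with an estimated correlation). Besides CXCL8, the chemokine genes CCL20 (2.65 ± 0.35), CXCL1 (1.90 ± 0.31) and CXCL2 (1.64 ± 0.32) led them. CCL20, CXCL1 and CXCL2, and CXCL10, IFI44 and SAMD9L named below, had a mean under 5 CPM over the 6 libraries. Among 48 secreted cytokines and growth factors, 14 rose and 2 fell (19 adjusted over the list alone; camera adjusted p = 9.81e-05, adjusted p = 0.285 with an estimated correlation), with the interferon-induced chemokine CXCL10 at 2.47 ± 0.49. This list shares CXCL8, CXCL1, CXCL2 and CCL20 with the NF-kB list and DKK1 and BMP4 with the Wnt list, among others. IER3 is in the NF-kB and immediate early lists, and ATF3 in the ATF4 and immediate early lists. Of 34 interferon-stimulated genes, 8 rose and 1 fell (12 adjusted over the list alone; camera adjusted p = 0.000153, adjusted p = 0.446 with an estimated correlation). IFI44 (2.38 ± 0.47) and SAMD9L (1.69 ± 0.34) were among them, and both calls ended without siRAB3IP replicate 2, that of IFI44 also without control replicate 1. Of 22 immediate early genes, which respond to stimuli without new protein synthesis, 10 rose (12 adjusted over the list alone; camera adjusted p = 1.03e-07, adjusted p = 0.446 with an estimated correlation), including IER3 (1.02 ± 0.10), FOSL1 (7.20 to 14.4 CPM) and ATF3 (0.91 ± 0.11). Of 14 blood-cell markers listed, 5 passed the filter, with a median of 0.65 CPM in control. Among these 5, 2 rose (3 adjusted over the list alone; camera adjusted p = 0.0087, adjusted p = 0.285 with an estimated correlation). They were the actin-bundling LCP1, from 1.24 to 4.33 CPM, and the alpha globin HBA2, from 0.454 to 1.22 CPM. HBA2 may share reads with HBA1, and whether it does was not tested. The call of HBA2 ended without siRAB3IP replicate 1, siRAB3IP replicate 2 or control replicate 2.

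ATF4 targets, endoplasmic reticulum stress, hypoxia, autophagy and ribosomal protein genes were further lists that camera called higher, and the heat shock list was not called. Of 14 heat shock genes 1 fell, HSPB1 at -0.71 ± 0.10 (1 adjusted over the list alone; camera adjusted p = 0.689, adjusted p = 0.931 with an estimated correlation). Of 28 targets of ATF4, the transcription factor of the integrated stress response, 13 rose and 1 fell (17 adjusted over the list alone; camera adjusted p = 5.54e-10, adjusted p = 0.206 with an estimated correlation). CHAC1, which degrades glutathione, rose 4.02-fold, the phosphatase subunit PPP1R15A rose 2.22-fold and the cystine transporter SLC7A11 rose 1.96-fold. Of 19 genes of the endoplasmic reticulum stress response, 11 rose (12 adjusted over the list alone; camera adjusted p = 2.75e-09, adjusted p = 0.206 with an estimated correlation), led by the transcription factor XBP1 (0.86 ± 0.08), the mannosidase-like EDEM1 (0.58 ± 0.08) and the chaperone HYOU1 (0.57 ± 0.08). Of 23 hypoxia and glycolysis genes, 6 rose and 2 fell (10 adjusted over the list alone; camera adjusted p = 0.000668, adjusted p = 0.206 with an estimated correlation), with adrenomedullin, ADM (0.95 ± 0.11), hexokinase HK2 (0.84 ± 0.09) and the glucose transporter SLC2A1 (0.60 ± 0.10) higher. Of 32 autophagy and lysosome genes, 7 rose and 1 fell (13 adjusted over the list alone; camera adjusted p = 0.00423, adjusted p = 0.572 with an estimated correlation), with the cargo receptor SQSTM1 at 0.66 ± 0.12. Of 65 cytosolic ribosomal proteins, 7 rose (7 adjusted over the list alone; camera adjusted p = 8.46e-06, adjusted p = 0.776 with an estimated correlation), with a median log2 fold change of 0.14. The 4 ribosomal genes with the largest rises, RPS24, RPS19, RPL22 and RPL26, each lost the call without siRAB3IP replicate 1 or control replicate 2, and all but RPS24 without siRAB3IP replicate 2.

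Mitotic, histone, Wnt and cholesterol synthesis genes were the lists that camera called lower. Of 31 mitotic genes, 6 fell (8 adjusted over the list alone; camera adjusted p = 0.00892, adjusted p = 0.572 with an estimated correlation), among them the hyaluronan receptor HMMR, from 90.4 ± 1.97 to 51.9 ± 6.43 CPM, and the kinesin KIF20A (-0.45 ± 0.08). Of 17 genes of the replication-dependent histone list, 7 fell (8 adjusted over the list alone; camera adjusted p = 5.51e-06, adjusted p = 0.671 with an estimated correlation). The libraries were made from poly(A) RNA, and how fully they read histone mRNAs was not tested. Among them were H1-3 (-0.74 ± 0.19), H3C4 (-0.57 ± 0.12) and H2BC4 (-0.46 ± 0.13), each lost without siRAB3IP replicate 2 or control replicate 1 and, except H3C4, by DESeq2 and with the length and GC trend removed. H2BC4 lost it by limma-voom too, and H1-3 without control replicate 2 or either siCAMSAP1 library. Of 17 Wnt targets, 5 fell and 1 rose (8 adjusted over the list alone; camera adjusted p = 0.00123, adjusted p = 0.206 with an estimated correlation). The stem-cell receptor LGR5 (-1.56 ± 0.21, mean under 5 CPM), CCND1 and BMP4 (-0.91 ± 0.16) fell, and the secreted Wnt inhibitor DKK1 rose (1.23 ± 0.20). Of 25 cholesterol synthesis genes, 7 fell and 2 rose (12 adjusted over the list alone; camera adjusted p = 0.0411, adjusted p = 0.776 with an estimated correlation), with the reductase TM7SF2 at -0.73 ± 0.09.

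Splicing and RNA processing genes changed singly. Of 27 hnRNP and related genes, 3 fell and 1 rose (6 adjusted over the list alone; camera adjusted p = 0.139, adjusted p = 0.776 with an estimated correlation), the largest change being that of HNRNPF, from 477 to 274 CPM (-0.80 ± 0.09). Of 22 SR proteins and their kinases, 2 fell (3 adjusted over the list alone; camera adjusted p = 0.168, adjusted p = 0.776 with an estimated correlation), SRSF12 (-0.65 ± 0.12) and TRA2A (-0.30 ± 0.08), the latter lost without any 1 of the siRAB3IP or control libraries and by DESeq2 on the 4 libraries. In the core spliceosome (44 genes), 3' end processing and export (29), nonsense-mediated decay (15) and RNA interference (13) lists, 1 gene each rose: the helicases DDX46 and DDX39A, SMG5 and DICER1. The camera adjusted p of these lists were 0.770, 0.879, 0.849 and 0.689, with adjusted p of 0.933, 0.933, 0.933 and 0.845 with an estimated correlation, and all 4 calls ended without siRAB3IP replicate 1. That of DDX39A also ended without control replicate 2, and that of DICER1 without siRAB3IP replicate 2 or control replicate 1. G1/S and p53 genes moved both ways. Of 37 DNA replication and G1/S genes, 6 rose and 1 fell (8 adjusted over the list alone; camera adjusted p = 0.252, adjusted p = 0.860 with an estimated correlation), with the transcription factor E2F1 at 0.59 ± 0.08. Of 22 p53 targets, 7 rose and 3 fell (13 adjusted over the list alone; camera adjusted p = 0.428, adjusted p = 0.845 with an estimated correlation), with the death receptor FAS (0.84 ± 0.12), which overlaps ACTA2, and GADD45A (0.67 ± 0.10) higher and the stress-induced SESN1 (-0.79 ± 0.08) and the DNA repair gene XPC (-0.54 ± 0.09) lower. The median of the p53 list was -0.01 and its mean 0.06, and the sign of the median depended on the scaling. Besides FAS, the genes SLC7A11, HK2, SQSTM1, TM7SF2, CCND1, HMMR, KIF20A, RPL22, DDX46, DICER1, XPC and IER3 overlap another gene, and their values are uncertain for the same reason as that of DNAH17.

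Of the 14 lists that camera called with its preset correlation, none was called with an estimated correlation, and the preset test also called lists in the grouping by sample records. Fry, which asks whether a list moved one way without setting it against other genes, called 8 lists. They were NF-kB targets, cytokines, endoplasmic reticulum stress, ATF4 targets, hypoxia, Wnt targets, blood-cell markers and RAB3IP trafficking, the last not called by camera. Some of these lists share members, so they are not separate results. The interferon, immediate early, ribosomal, autophagy, mitotic, histone and cholesterol lists passed neither fry nor camera with an estimated correlation.

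IL32, TNFRSF9 and RELB also rose in the siCAMSAP1 libraries, where fewer genes passed the threshold. IL32 rose 4.16-fold, from 15.2 ± 1.31 to 63.3 ± 0.497 CPM (SD, n = 2 each), TNFRSF9 rose 3.21-fold and RELB 2.91-fold. The adhesion receptor ICAM1 rose 2.45-fold and FSTL3, a secreted binder of activin, 2.30-fold. TAGLN, an actin-binding protein of smooth muscle, rose from 1.80 ± 0.361 to 7.32 ± 1.97 CPM. SHISA2, an inhibitor of Wnt and FGF receptors, fell from 83.4 ± 6.45 to 30.5 ± 4.60 CPM, and the membrane-curving PACSIN2 and the microtubule-associated MAP1A fell 1.94-fold and 2.14-fold.

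Of 22331 genes, 237 differed between siCAMSAP1 and control by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 116 rose, 121 fell and 30 changed over 2-fold. Calls were 48.9% higher with TMM scaling and 38.5% higher with upper-quartile scaling, which called 265 genes. Over 17 alternatives the count ran from 39, against a minimum fold of 1.2, to 1643, with a replicate block. At a mean of at least 5 CPM, the largest log2 rises were those of IL32 (2.06 ± 0.09), TNFRSF9 (1.68 ± 0.17), RELB (1.54 ± 0.16), ICAM1 (1.29 ± 0.16), FSTL3 (8.60 to 19.8 CPM), the cytokine receptor IL31RA (0.97 ± 0.15), SLC9A2 (0.89 ± 0.17), the adaptor subunit AP1M2 (0.88 ± 0.13), the NF-kB inhibitor NFKBIA (0.86 ± 0.12) and SHISAL1 (0.86 ± 0.13). The largest falls were those of SHISA2 (-1.45 ± 0.15), the secreted calcium binder SMOC1 (-1.40 ± 0.23), OLFM1 (-1.23 ± 0.25), MAP1A (-1.10 ± 0.17), the laminin chain LAMA4 (-0.98 ± 0.18), LRATD2 (-0.98 ± 0.12), the netrin receptor UNC5C (-0.98 ± 0.19), the smooth muscle actin ACTA2 (-0.96 ± 0.17), which overlaps FAS, METTL7A (-0.96 ± 0.13) and PACSIN2 (-0.95 ± 0.09). Calls ended for SLC9A2 without control replicate 2 or siCAMSAP1 replicate 2, for SHISA2 without either control, for SMOC1 without siCAMSAP1 replicate 1, for OLFM1 without control replicate 1 or siCAMSAP1 replicate 2, and for LAMA4, UNC5C and ACTA2 without control replicate 2 or siCAMSAP1 replicate 1. They also ended with a stricter filter for OLFM1, LAMA4 and UNC5C, by limma-voom for OLFM1, and with only the compared groups in the fit for OLFM1 and SLC9A2. The count of called genes was 425 without control replicate 1, 135 without control replicate 2, 127 without siCAMSAP1 replicate 1 and 86 without siCAMSAP1 replicate 2.

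NF-kB and YAP/TEAD targets were the groups with the most rises in siCAMSAP1 among calls adjusted over all genes. Adjusted over the list alone, the extracellular matrix and integrin list had the most. Of 21 NF-kB targets, 7 rose (11 adjusted over the list alone; camera adjusted p = 6.16e-24, adjusted p = 0.222 with an estimated correlation), RELB, ICAM1, NFKBIA and the subunit NFKB2 (0.83 ± 0.12) ahead of the others. Of 18 targets of the YAP and TEAD regulators, 4 rose (9 adjusted over the list alone; camera adjusted p = 3.09e-10, adjusted p = 0.222 with an estimated correlation). These were FJX1 (0.52 ± 0.12), WTIP (0.51 ± 0.11), AJUBA (0.43 ± 0.08) and AMOTL2 (0.40 ± 0.08), and each call ended without control replicate 2, siCAMSAP1 replicate 1 or siCAMSAP1 replicate 2, that of WTIP also without control replicate 1. With only the compared groups in the fit FJX1, WTIP and AMOTL2 lost their calls, FJX1 and WTIP also with upper-quartile scaling or a stricter filter, and FJX1 by limma-voom. Among 9 markers of keratin-rich epithelium that passed the filter, of 14 listed, 1 rose, the laminin chain LAMB3, though not without siCAMSAP1 replicate 1 (3 adjusted over the list alone; camera adjusted p = 5.44e-06, adjusted p = 0.222 with an estimated correlation). Among 22 immediate early genes, 1 rose, IER3 at 0.74 ± 0.10 (7 adjusted over the list alone; camera adjusted p = 1.11e-06, adjusted p = 0.503 with an estimated correlation), and of 34 interferon-stimulated genes 2 rose, the transcription factor IRF1 (0.67 ± 0.10) and OAS3 (5 adjusted over the list alone; camera adjusted p = 0.00225, adjusted p = 0.543 with an estimated correlation). OAS3 lost its call without siCAMSAP1 replicate 1. Of 48 secreted cytokines and growth factors, 1 fell, the growth factor FGF9 at -0.93 ± 0.19 (1 adjusted over the list alone; camera adjusted p = 0.257, adjusted p = 0.768 with an estimated correlation). FGF9 lost its call without control replicate 2, siCAMSAP1 replicate 1 or siCAMSAP1 replicate 2, and with only the compared groups in the fit. Of 5 blood-cell markers that passed the filter, of 14 listed, 1 rose, LCP1 at 1.10 ± 0.23 (1 adjusted over the list alone; camera adjusted p = 0.0416, adjusted p = 0.359 with an estimated correlation). LCP1 lost its call without siRAB3IP replicate 2, control replicate 1 or either siCAMSAP1 library, by limma-voom, and with only the compared groups in the fit. The endoplasmic reticulum stress list was called by camera (adjusted p = 0.00183, adjusted p = 0.359 with an estimated correlation) with 17 of 19 members above 0 and a median of 0.14. This was a call of the list and not of single members. The autophagy and lysosome list was also called higher by camera (adjusted p = 3.01e-05, adjusted p = 0.359 with an estimated correlation), with 27 of 32 members above 0 and a median of 0.12. Between the knockdowns camera did not call that list (adjusted p = 0.948, adjusted p = 0.996 with an estimated correlation). The extracellular matrix and integrin list was called higher by camera, with 24 of 37 members above 0 and a median of 0.15, although 2 members fell and 1 rose (12 higher and 4 lower, 16 in all, adjusted over the list alone; camera adjusted p = 0.0455, adjusted p = 0.768 with an estimated correlation). The collagen COL5A2 (-0.80 ± 0.11) and LAMA4 fell and the collagen COL18A1 (0.50 ± 0.10) rose. The call of COL18A1 ended without control replicate 2, siCAMSAP1 replicate 1 or siCAMSAP1 replicate 2, with a stricter filter, and with the length and GC trend removed.

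Some p53 targets fell in siCAMSAP1. Of 22 members, 4 fell and the other 18 did not pass (7 adjusted over the list alone; camera adjusted p = 3.01e-05, adjusted p = 0.359 with an estimated correlation): the DNA damage sensor DDB2 (-0.63 ± 0.10), the cyclin-dependent kinase inhibitor CDKN1A (-0.58 ± 0.11), the p53 ligase MDM2 (-0.48 ± 0.09) and SESN1 (-0.42 ± 0.08). The last 3 lost their calls without siCAMSAP1 replicate 2, MDM2 and SESN1 also without siCAMSAP1 replicate 1, and SESN1 without control replicate 2. CDKN1A and SESN1 also lost theirs with only the compared groups in the fit. Of 28 ATF4 targets, 2 fell and 1 rose (10 adjusted over the list alone; camera adjusted p = 0.0191, adjusted p = 0.551 with an estimated correlation). ALDH1L2 (-0.72 ± 0.14) and PSAT1 (-0.38 ± 0.08) fell and PPP1R15A (0.64 ± 0.11) rose. ALDH1L2 lost its call without control replicate 2 or siCAMSAP1 replicate 1, and PSAT1 without any 1 of the 6 libraries, by limma-voom and with the length and GC trend removed. Both lost theirs with only the compared groups in the fit. Of 17 Wnt targets, 1 fell, SOX4 at -0.55 ± 0.10 (4 adjusted over the list alone; camera adjusted p = 0.00532, adjusted p = 0.343 with an estimated correlation), a call that ended without siCAMSAP1 replicate 2. The TGF-beta list was not called (camera adjusted p = 0.508, adjusted p = 0.768 with an estimated correlation), and its 20 members went both ways, TAGLN (2.02 ± 0.23) rising and ID3 (-0.58 ± 0.09) falling, ID3 not without siCAMSAP1 replicate 2. TAGLN overlaps PCSK7, PACSIN2 overlaps ARFGAP3 and MDM2 overlaps CPM (the carboxypeptidase M gene), so their values are uncertain. Camera called 12 lists here, 7 without siCAMSAP1 replicate 2, and none with an estimated correlation, and fry called none.

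**Figure D2:**
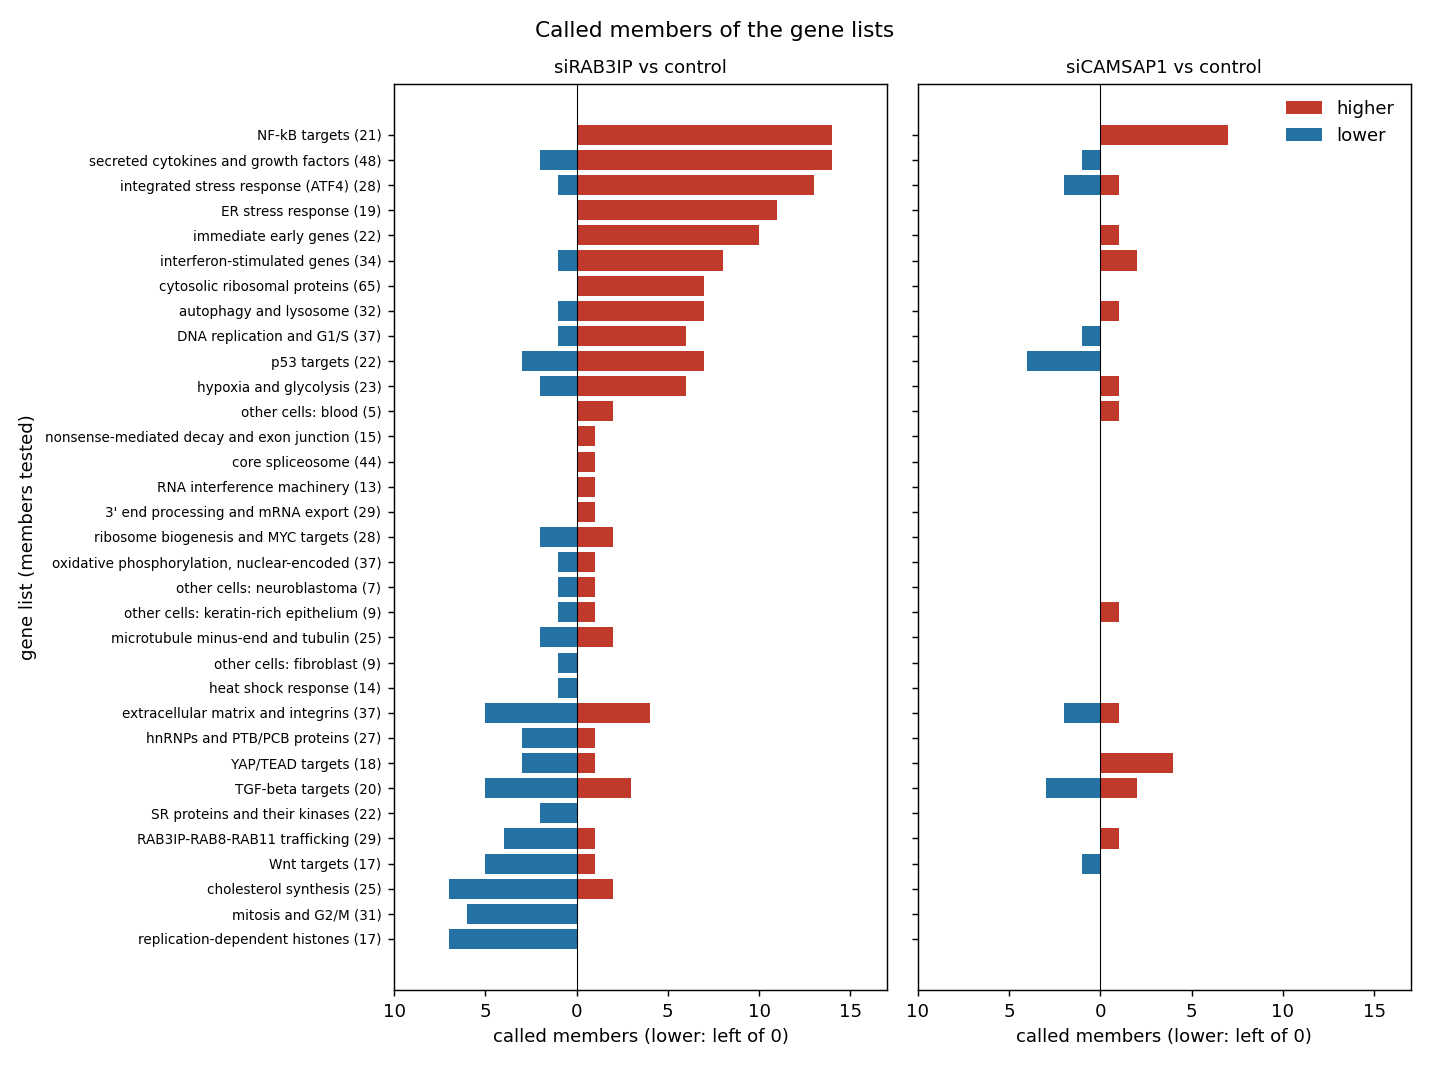
Members of each gene list that passed an adjusted p of 0.05 in siRAB3IP against control (left) and siCAMSAP1 against control (right), higher drawn to the right of 0 and lower to the left, with the number of members tested in brackets after each list name. In the NF-kB list 14 of 21 members were higher in siRAB3IP and 7 in siCAMSAP1.

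Set against each other, the knockdowns differed in ATF4 targets, histone and ribosomal protein genes, p53 and YAP/TEAD targets and secreted cytokines, among other lists. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2076 of 22331 genes differed, 1148 higher and 928 lower in siRAB3IP, 296 of them over 2-fold. With a replicate block the count was 4829. At a mean of at least 5 CPM, the largest differences above 0 were those of OLFM1 (2.62 ± 0.24), BMP2 (1.70 ± 0.10), the lymphatic growth protein CCBE1 (1.62 ± 0.23), DNAH17 (1.61 ± 0.11) and SMOC1 (1.61 ± 0.23), and below 0 those of SGPL1 (-1.66 ± 0.09), the collagen COL27A1 (-1.40 ± 0.16), CXXC4 (-1.40 ± 0.28), RASSF2 (-1.34 ± 0.16) and MARCKS (-1.29 ± 0.09). CXXC4 lost its call without siRAB3IP replicate 1. Of 28 ATF4 targets, 16 were higher in siRAB3IP (19 adjusted over the list alone; camera adjusted p = 8.52e-18, adjusted p = 0.380 with an estimated correlation), with CHAC1 at 1.97 ± 0.30 (mean under 5 CPM), SLC7A11 at 1.14 ± 0.12, the asparagine synthetase ASNS at 0.94 ± 0.08 and the alanyl-tRNA synthetase AARS1 at 0.74 ± 0.08. Of 22 p53 targets, 7 were higher and 2 lower (14 adjusted over the list alone; camera adjusted p = 0.000103, adjusted p = 0.385 with an estimated correlation), with CDKN1A at 0.84 ± 0.11 and the nuclease AEN at 0.55 ± 0.08. Of 18 YAP/TEAD targets, 6 were lower (6 adjusted over the list alone; camera adjusted p = 0.00014, adjusted p = 0.385 with an estimated correlation), with WTIP at -0.97 ± 0.11 and AJUBA at -0.65 ± 0.08. TAGLN differed by -1.98 ± 0.23 and the collagen COL1A1 by -1.03 ± 0.14. Of 17 histone genes, 5 were lower (8 adjusted over the list alone; camera adjusted p = 1.2e-06, adjusted p = 0.631 with an estimated correlation), and H3C4, H2AC11, H2BC4 and HIST1H3B each lost the call without siRAB3IP replicate 2 or siCAMSAP1 replicate 1. H2BC4 lost it also with RLE scaling, by DESeq2, by limma-voom and with the length and GC trend removed. The limit of poly(A) libraries for histone mRNAs holds here too. Of 25 cholesterol synthesis genes 7 were lower and 1 higher (13 adjusted over the list alone; camera adjusted p = 0.00705, adjusted p = 0.693 with an estimated correlation), with HMGCS1 at -0.60 ± 0.08. Of 65 cytosolic ribosomal proteins, 8 were higher (9 adjusted over the list alone; camera adjusted p = 1.4e-06, adjusted p = 0.693 with an estimated correlation). Their 4 largest differences, RPS19, RPL22, RPS24 and RPL4, each lost the call without siRAB3IP replicate 1, siRAB3IP replicate 2 or siCAMSAP1 replicate 1. All but RPL22 lost it without siCAMSAP1 replicate 2, and RPS24 and RPL4 with the length and GC trend removed. Of 48 secreted cytokines and growth factors, 8 were higher and 1 lower (18 adjusted over the list alone; camera adjusted p = 0.00274, adjusted p = 0.385 with an estimated correlation), BMP2 among them. Of 9 markers of keratin-rich epithelium that passed the filter, of 14 listed, 1 was lower, KRT19 at -0.46 ± 0.10 (1 adjusted over the list alone; camera adjusted p = 0.0294, adjusted p = 0.385 with an estimated correlation), and the median of the list was -0.52. KRT19 lost its call without siRAB3IP replicate 1, siRAB3IP replicate 2 or siCAMSAP1 replicate 1. Of 19 endoplasmic reticulum stress genes, 6 were higher (6 adjusted over the list alone; camera adjusted p = 0.000179, adjusted p = 0.385 with an estimated correlation), XBP1 at 0.72 ± 0.08 among them. Of 23 hypoxia and glycolysis genes, 6 were higher and 1 lower (8 adjusted over the list alone; camera adjusted p = 0.0106, adjusted p = 0.385 with an estimated correlation), with SLC2A1 at 0.57 ± 0.10. Of 31 mitotic genes, 6 were lower (7 adjusted over the list alone; camera adjusted p = 0.0144, adjusted p = 0.631 with an estimated correlation), with HMMR at -0.70 ± 0.09. Of 37 DNA replication and G1/S genes, 6 were higher and 1 lower (9 adjusted over the list alone; camera adjusted p = 0.0294, adjusted p = 0.766 with an estimated correlation). The list was called higher, with 24 of 37 members above 0 and a median of 0.07. CCNE1, which encodes cyclin E1, was the member that went the other way, at -0.73 ± 0.13. Of 21 NF-kB targets, 4 were higher and 1 lower (9 adjusted over the list alone; camera adjusted p = 0.0359, adjusted p = 0.693 with an estimated correlation). The count of called genes was 1132 without siRAB3IP replicate 1, 719 without siRAB3IP replicate 2, 976 without siCAMSAP1 replicate 1, 1261 without siCAMSAP1 replicate 2, and 520 against a minimum fold of 1.2.

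Some genes passed against control in both knockdowns. TNFRSF9, IL32, RELB, ICAM1, NFKBIA, NFKB2, FSTL3, IER3 and PPP1R15A rose in both, and LRATD2, METTL7A, MAP1A and LAMA4 fell in both, whereas OLFM1 rose in siRAB3IP and fell in siCAMSAP1. In all, 81 genes were higher in both, where independent lists of the same sizes would share 7.6, and 34 were lower in both, where they would share 6.5. In 20 simulations of unchanged groups sharing their controls, 0.2 genes on average were higher in both and 0.05 lower in both, at most 1 each. Shared controls raise such counts above those of independent lists. No gene was changed in the simulations, so by how much they raise them beside real changes was not measured. With opposite signs there were 14, where independent lists give 14.2. The counts in the same direction, 115 in sum, became 232 without control replicate 1, 65 without control replicate 2, 71 without siCAMSAP1 replicate 1 and 53 without siCAMSAP1 replicate 2. With a replicate block they came to 858. Across all 22331 genes, which are not independent replicates, the log2 fold changes correlated at 0.435, against 0.497 in 20 simulations of unchanged groups. With 1 library left out the correlation ran from 0.327 to 0.614, and it was 0.614 and 0.61 without control replicate 1 or 2. No simulation was made with a library left out, so 0.497 is no measure for those values. With all 6 libraries the covariance of the log2 fold changes was 0.0885 against a simulated 0.0466, a difference of 0.0418. Both comparisons use the same 2 control libraries, and a split with 1 control library per knockdown was not made. What the shared controls add to the overlap was therefore not taken out.

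**Figure D3:**
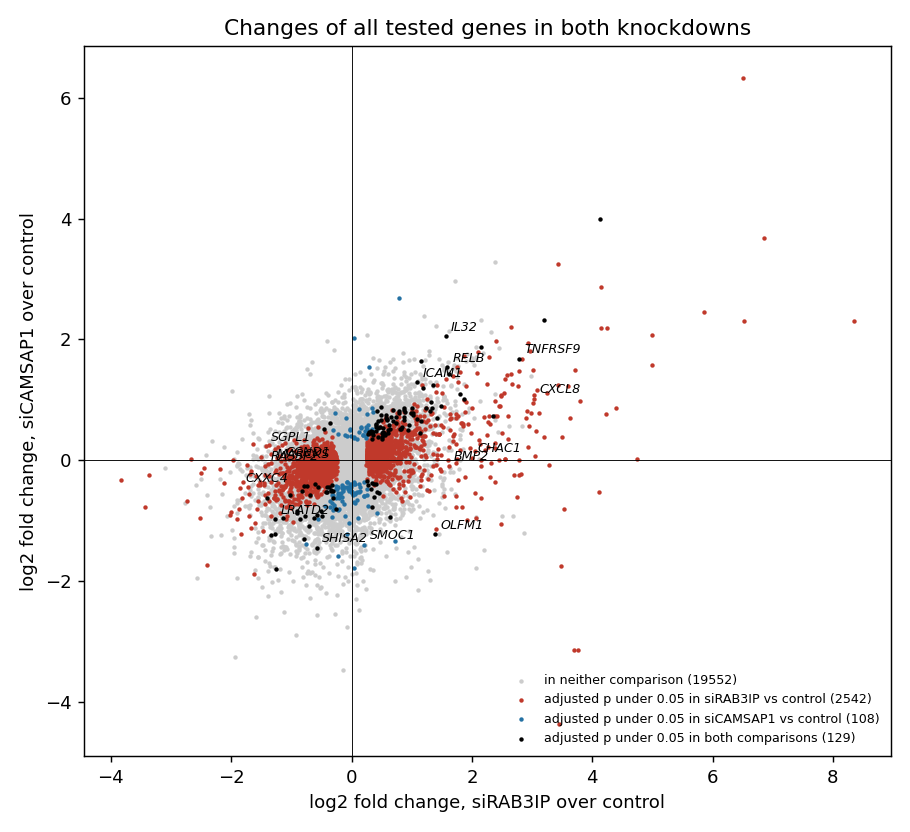
Log2 fold change of every tested gene in siRAB3IP over control (horizontal axis) and in siCAMSAP1 over control (vertical axis), 1 point per gene, coloured by the comparison in which the adjusted p was under 0.05. IL32, RELB, ICAM1 and TNFRSF9 lie in the upper right, and 129 genes passed in both comparisons.

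The authors' deposited tables hold 2192 genes for siRAB3IP (1306 higher and 886 lower) and 474 for siCAMSAP1 (255 and 219), each with an adjusted p of 0.05 or less. All 2192 and all 474 had the same sign here when the libraries carried the names of the tables, and 1928 (88.0%) and 215 (45.4%) were also called by edgeR. With the grouping by sample records, 129 of the 2192 genes (5.9%) and 418 of the 474 (88.2%) had the same sign. DESeq2 run on the 4 libraries of each comparison called 2010 and 282 genes. These tables were made from the same libraries and are no independent check.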

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

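The tests of the label conflict below were chosen only after the result was seen.

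For 4 of the 6 libraries, the name in the authors' deposited tables differs from the group or number of the sample record that lists the library, a signal in columns that the planned comparisons did not use. Grouped by sample records, edgeR called 0 genes in each comparison (330, 437 and 456, or 1.48%, 1.96% and 2.04%, at an unadjusted p under 0.05, and 0, 1 and 0 by DESeq2). Grouped by table names, edgeR called 2671, 237 and 2076.

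Library identifiers attached to the wrong samples in the sample records would leave a single good division of the libraries into pairs. Of 15 divisions, 1, that of the deposited tables, gave 4984 called genes over the 3 comparisons, and the highest other gave 3519, but 15 splits are too few for a share under 0.05. Each library was also set against the other 5 for 3' UTR words: 4 knockdown libraries had the same pair of lowest words as their partner in the deposited tables, and no other library had it. Too little depth or too few libraries is argued against by the 2671 genes that the same libraries gave when regrouped. The library recorded as control replicate 2 had z of -9.79 and -9.65 for TGACTTA and GACTTAA, against 5.95 and 7.29 in its recorded partner. That recorded as circRAB3IP replicate 2 had 4.98 and 3.92 for ACATCCC and CATCCCA, against -9.18 and -9.84 in its recorded partner. These values argue against the recorded pairs for these libraries. Wrong identifiers in the records may therefore account for the 0 calls, although the siRNA of each pair was not settled by these values. The low words differ between the pairs. TGACTTA lies in windows at RAB3IP exon ends and ACATCCC in those of CAMSAP1, whereas GACTTAA and CATCCCA, which overlap them, lie in neither. Of all words 8.2% and 8.9% lie in such windows too, and the siRNA sequences were not used here. A biological explanation was not tested.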

How the results depend on the processing

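The table-name grouping and every alternative under it, the removal of the length and GC trend among them, were chosen after seeing the data, and those under sample records were planned. Where a value changed, the cause was not tested unless stated.

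With table names, siRAB3IP against control (2671 genes) kept its count within 1.5 times under RLE, upper-quartile scaling, no filter, the stricter filter, the 2 compared groups alone, DESeq2, limma-voom and removal of the length and GC trend (2388 to 3274). It became 5590 with a replicate block and 702 with glmTreat, which asks for more than a fold of 1.2 by construction. Leaving out 1 library gave 1160 to 2675, with 1307 and 1160 without siRAB3IP replicates 1 and 2 and 1680 without control replicate 2. A lone library is assumed to vary like the other groups. siCAMSAP1 against control (237) became 676 with no filter, 152 with the compared groups alone, 1643 with a replicate block, 361 with DESeq2, 359 with the trend removed and 39 with glmTreat. Leaving out 1 library gave 86 to 425. The direct comparison (2076) became 4829 with a replicate block and 520 with glmTreat, and 719 to 2652 with 1 library left out. The differences between replicates 1 and 2 correlated across genes between groups at 0.148, 0.15 and 0.11 with table names and at -0.123, -0.328 and -0.081 with sample records. With 2 libraries per group this does not settle whether the numbers pair the libraries, so the replicate block stays an alternative, and the simulations of unchanged groups held no pairing.

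Gene lists called by camera (14, 12 and 13) became 0, 0 and 0 with an estimated correlation and 8, 0 and 0 with fry. Leaving out 1 library gave 13 to 16, 7 to 15 and 11 to 15. Genes called in both knockdowns in the same direction (115) became 306 with no filter, 858 with a replicate block and 186 with the trend removed, and 53 to 232 with 1 library left out. The correlation between knockdowns (0.435) lay between 0.327 and 0.614 with 1 library left out.

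With sample records, edgeR called 0 genes per comparison (330, 437 and 456, or 1.48%, 1.96% and 2.04%, at an unadjusted p under 0.05). With no filter it called 5, 21 and 14. DESeq2 called 1 in circCAMSAP1 against control, and the compared groups alone gave 1 between knockdowns. Leaving out 1 library gave 0 to 1, 0 to 4 and 0 to 2. The table names gave 2671, 237 and 2076. Lists called by camera (10, 11 and 8) became 0, 0 and 0 with an estimated correlation and with fry, 6 to 14, 9 to 13 and 8 to 13 with 1 library left out, and 13 between knockdowns with table names. The overlap went from 0 to 115 with table names. The correlation (0.443) lay between 0.192 and 0.725 with 1 library left out.

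The log2 fold change of CAMSAP1 in siCAMSAP1, 0.02, was 0.00 with upper-quartile scaling. That of RAB3IP in siCAMSAP1, -0.03, was 0.03 without control replicate 2, without siCAMSAP1 replicate 1 and with the trend removed, and between -0.09 and 0.03 with 1 library left out. Of the named calls, 61 of 117 in siRAB3IP, 21 of 49 in siCAMSAP1 and 40 of 106 between knockdowns stayed with every library left out in turn.

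Depth set the floor of 3 counts at 0.0757 to 0.0803 CPM, and 167 of the 2671 genes lay under 1 CPM.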

Other observations

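The tests of gene length with GC content, of seed matches, and of the words of one knockdown in the other were chosen only after the counts of called genes were seen.

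Genes near the host genes in function changed singly in siRAB3IP. Of 29 genes of RAB3IP, RAB8 and RAB11 trafficking, 4 fell and 1 rose (7 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.273, adjusted p = 0.572 with an estimated correlation), the small GTPase RAB8B (-0.54 ± 0.09) and the exocyst subunit EXOC1 (-0.49 ± 0.08) among the falls. Fry called this list lower. Of 25 microtubule genes, 2 rose and 2 fell (4 adjusted over the list alone; camera adjusted p = 0.652, adjusted p = 0.776 with an estimated correlation), with CAMSAP2, a paralog of CAMSAP1, at 0.37 ± 0.08, a call lost without siRAB3IP replicate 1. ODC1, which starts polyamine synthesis, fell from 291 to 140 CPM, the respiratory subunit COX6B1 from 122 to 63.1 CPM, and the small heat shock protein HSPB1 from 83.0 to 50.9 CPM. KATNAL1, a microtubule-severing subunit, was higher in siRAB3IP than in siCAMSAP1 (0.62 ± 0.11).

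Many genes were called between siRAB3IP and control. A bias with gene length and GC content between libraries is argued against by the trend itself: after its removal 2598 of the 2671 genes (97.3%) were still called with the same sign. Off-target binding of the siRNA through its seed would lower genes with a matching word in the 3' UTR. The lowest of all 7-base words in siRAB3IP was GACTTAA (z = -10.21, lowest shuffled value -4.91), and it was not in the windows at the ends of RAB3IP exons, whereas the next, TGACTTA (-9.92), was, as were 8.2% of all words. These words overlap and join into TGACTTAA. The missing window match of GACTTAA therefore does not by itself count against a seed match. Of 536 genes with TGACTTAA, SGPL1, CCND1, RASSF2, HNRNPF, SESN1, RAB8B and WTIP among them, 115 were called lower and 29 higher, against 760 and 1092 of 10751 with neither word. A seed effect may therefore add to the falls, cannot be told apart from other causes without the siRNA sequence, and leaves most called genes, which lack the words, open.

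In siCAMSAP1 the lowest word was ACATCCC (z = -10.7, lowest shuffled value -4.64), which is in the windows of CAMSAP1, as were 8.9% of all words. The next, CATCCCA (-9.95), was not in them, but it overlaps ACATCCC and joins with it into ACATCCCA. Of 366 genes with ACATCCCA, MAP2, MAP1A and PACSIN2 among them, 20 were called lower, against 55 of 10714 with neither word. MAP2 (-1.34) and MAP1A (-0.71) were also called lower in siRAB3IP, so the word of siCAMSAP1 does not separate their falls from a shared one. The words of each knockdown had z between -0.41 and 1.73 in the other. Seed matches may account for part of the falls in siCAMSAP1, but cannot be told apart from other causes without the siRNA sequence. A biological effect of the circular RNA stays open and untested. IL32, TNFRSF9 and RELB rose in both knockdowns, and a response to siRNA as such was not tested.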
